A study of Caenorhabditis elegans with 2 samples.

How the data were processed

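Peaks of CEH-18 tagged with GFP were measured by chromatin immunoprecipitation and sequencing, in whole late embryos of the strain OP533, collected 3 h after synchronisation by bleaching. The description in the labels gives an antibody against GFP and their antibody field gives ceh-18, and the first was taken as the method. The labels name 2 biological replicates, 1 library each, which form 1 group. Whether these came from separate cultures is not stated beyond the word biological, so agreement between them may in part be technical.

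The deposited files are peak lists in the narrowPeak format, on the ce10 and ce11 builds. Per the labels and the notes deposited with the lists, the authors made a list for each replicate, a list from both replicates pooled (peaks and background given to the irreproducible discovery rate, IDR, step) and a list thresholded by IDR, all from alignments of the immunoprecipitated reads and of a control. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the deposited height from the authors' peak caller, on a scale that is not stated, and was used only to describe, rank or filter peaks within a list. The -log10 q of each peak is as deposited by the authors, and 1912 thresholded ce11 peaks shared its highest value, so peaks were ranked by signal. Read counts were not used here, so depth is unknown. Replicate 1's list had exactly 30000 peaks in both builds, which may reflect a limit on its length.

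The ce11 lists were the main data. They were annotated with the WBcel235 assembly, which is the same build, and Ensembl release 115 genes, after checking that no peak passed a chromosome end. The ce10 lists gave counts only, since no ce10 sequence was used here, and no coordinates were compared between builds. The share of peaks on X in ce10 was tested against the ce11 share of length. All 2575 thresholded ce11 peaks were rows of the pooled list, and were all of its peaks with a signal of at least 114.217. They had 2539 distinct intervals, since a wide peak can hold several summits. In ce10 the thresholded list had 3485 peaks. Coordinates are 1-based.

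The tests, gene lists, motifs, naming rule and most alternatives were fixed before the data were examined. The number of peaks on X was tested with an exact binomial test. Shares of summits by annotation and near non-coding genes (within 200 bp) were compared with 100000 random placements on the same chromosomes, two-sided. Annotation classes were assigned in the order promoter window, 5′ UTR, coding exon, 3′ UTR, intron and intergenic. Overlap with replicates needed at least 1 bp and was compared with 1000 random placements. Each of 32 gene lists with at least 3 measured members was compared with all other protein-coding genes by Fisher's exact test, two-sided. Members of lists that are not protein-coding, such as microRNA genes, were not measured. Each of 12 motifs was searched on both strands within 75 bp of the summit and in 2 flanking windows of the same width centred 500 bp away, with an exact McNemar test against the flank at lower coordinates. The flank share is the mean of both flanks. Words of 6 bases were compared by Fisher's exact test. Adjusted p-values are Benjamini-Hochberg within each family, at 0.05. Genes and peaks are not independent replicates, so these tests describe this peak set.

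Named genes were those nearest to the 20 strongest peaks, the up to 4 members with the strongest peak of each list with more bound members, the strongest bound member of other lists, ceh-18, unc-119, ceh-6 and unc-86, and the 5 genes with most summits in their body and upstream intergenic sequence, of which 1 is not reported here. Alternatives were the other build, merged summits, the 1287 peaks with the highest signal, the strongest peaks of each replicate alone, other windows, controls and backgrounds, and upstream-distance-matched gene lists. A GC-matched control, the removal of summits near small RNA genes the length of the peak-free stretch over ceh-18 and the signal of peaks inside unc-119 were added after seeing the data.

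The tests were checked on simulated data. Of 100 random summit sets, 4 had p below 0.05 for the promoter share. In lists of 40 of the 19973 genes, a planted odds ratio of 12 was called in 100% of lists, 1 of 3 in 42.4%, and 1.18% of unplanted lists were called. An octamer planted in 5% of windows was called by the motif test, and no motif or word was called in unplanted windows. These windows lay at random positions, while real summit windows had a GC content of 47.6% against 35.1% in their flanks. The check therefore cannot show how many calls such a difference in base composition would give. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.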

Results

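Chromatin bound by CEH-18, a POU homeodomain transcription factor of the nematode Caenorhabditis elegans, was profiled by chromatin immunoprecipitation and sequencing in whole hermaphrodite embryos at a late stage. The worms carried an integrated transgene for CEH-18 fused at its C-terminus to green fluorescent protein (GFP), and the description in the labels gives an antibody against GFP, while their antibody field names ceh-18. Whether untagged CEH-18 was precipitated too is therefore not settled. The 2 biological replicates formed 1 group, so the design held no comparison between conditions. The questions addressed were where the tagged protein was detected, next to which genes, over which sequences and how alike the replicates were. The deposited files listed peaks and not reads, so the sequencing depth of each replicate is unknown and no interval for the signal of a peak can be given.

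The 2575 thresholded peaks on the ce11 build lay on all nuclear chromosomes, and the strongest were beside K12H4.5, tasp-1, cdc-48.1 and rpl-3. The highest signal of any peak was 1223, over III:8043766-8044184, with its summit in intergenic sequence 522 bp upstream of the gene K12H4.5 (WBGene00019680). It ranked 1 in both replicates, with a signal of 584 in replicate 1 and 646 in replicate 2. The next strongest summit, with a signal of 1150, lay 66 bp upstream of tasp-1. The next 2 summits lay 160 bp upstream of cdc-48.1, which encodes an AAA ATPase that unfolds ubiquitinated proteins, and 274 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Their signals were 911 over II:10563364-10563759 and 882 over III:3867377-3867789.

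Among the 20 strongest peaks, those of tos-1, the 14-3-3 gene ftt-2, rpl-35, Y39E4B.6, the PUF-family gene puf-9 and iff-2, which encodes a homologue of the translation factor eIF5A, also had summits in a promoter window. The strongest of these had a signal of 746, 106 bp upstream of tos-1. For sup-26, which encodes an RNA-binding protein, the peak of signal 661 lay 2018 bp upstream. Other strong peaks lay farther from any annotated protein-coding 5′ end. A summit of signal 711 was 6043 bp upstream of K02D3.1, and 1 of signal 630 was 4869 bp upstream of xol-1, the X-linked switch gene of sex determination. Peaks nearest to W02H3.3, C30E1.4, cest-16 and F20B6.9, all on X, had signals between 639 and 804. The summits nearest to ZK1248.17 and col-94 were within 200 bp of small nuclear RNA (snRNA) genes, and that nearest to W03C9.1 was within 200 bp of a small nucleolar RNA (snoRNA) gene.

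Chromosome X held 570 of the peaks, more than its length would give. This was 22.1% of all peaks (95% exact binomial interval 20.5% to 23.8%), against 17.7% of the nuclear genome's length (exact binomial test, two-sided, p = 7.9e-09). The density was 32.2 peaks per Mb on X and 24.3 on the autosomes together. Autosomes differed among themselves, from 17 peaks per Mb on V (exact Poisson interval 15.3 to 18.9) to 31.4 on III (28.5 to 34.5), so X was close to III and to I, which had 30.7. These intervals cover counting error only, and neighbouring peaks are not independent.

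Some genes gathered several summits over their body and upstream intergenic sequence. The most, 10, were at ppfr-1, which encodes a regulatory subunit of protein phosphatase 4, within 26.7 kb. There were 8 at egl-27, a homologue of the chromatin regulator MTA1, within 31.5 kb. Among the other genes reported here, daf-5 and Y39E4B.6 had 7 each. The promoter windows of ppfr-1, egl-27 and daf-5 held no summit. How many summits regions of this length would hold at random was not tested.

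Peaks were shared by the replicates. Replicate 1 listed 30000 peaks, a round number, and replicate 2 listed 21337. Of the thresholded peaks, 2568 (99.7%) were overlapped by a peak of replicate 1 and 2572 (99.9%) by a peak of replicate 2, against means of 23.4% and 17.2% over 1000 random placements. When only the 2575 strongest peaks of each replicate were used, 90% and 90.5% of the thresholded peaks were overlapped. Of replicate 1's 2575 strongest peaks, 2101 (81.6%) overlapped one of replicate 2's. The thresholded set was drawn from both replicates, so its overlap with either is not independent evidence of agreement.

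Across the 2565 peaks found in both replicates, signal was correlated, with a Spearman coefficient of 0.779 and a Pearson coefficient of 0.839 on the log2 scale. After each replicate's signals were divided by their median, 2531 peaks (98.7%) were within 2-fold between replicates, and the log2 ratio had an SD of 0.37. These values are across peaks, which are not independent replicates. The peaks were also chosen by their signal in the pooled list, to which both replicates contribute, so the values are not independent evidence of agreement either.

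**Figure D1:**
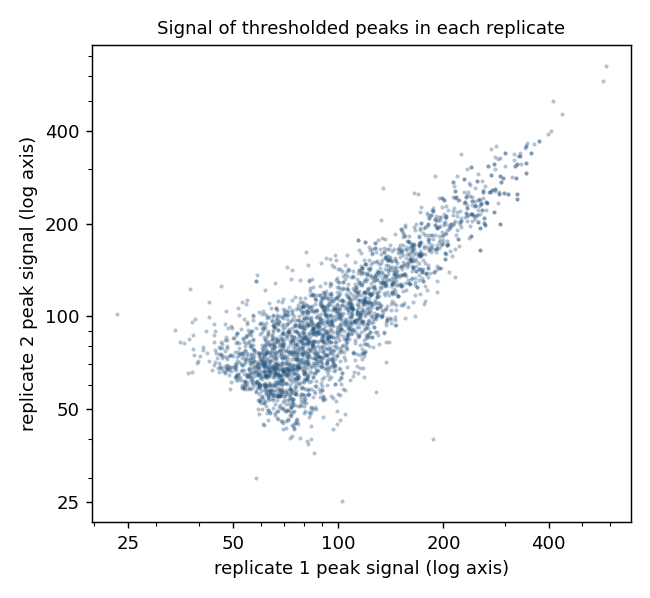
Signal of each thresholded peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the peak caller's own units, with 1 point per peak found in both. The 2565 points rise together, with a Spearman coefficient of 0.779.

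Summits lay in promoters and other non-coding sequence and rarely in coding exons. The window from 1000 bp upstream to 200 bp downstream of a protein-coding gene's 5′ end held 1152 summits, or 44.7% (95% exact interval 42.8% to 46.7%), against a mean of 20.9% for random placements (p = 1e-05, the smallest that 100000 placements can give, two-sided). Outside those windows, coding exons held 12 summits (0.466%, against 19.7% at random) and 3′ UTRs held 7 (0.272%, against 2.43%). Introns held 24.2%, against 31.1%, and intergenic sequence 29.1%, against 25%. Each of these 4 shares also had the smallest possible p. For 5′ UTRs the share was 1.17%, against 0.829% (p = 0.0631, permutation of summit positions), which did not pass.

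The median distance from a summit to the nearest protein-coding 5′ end was 1034 bp, and 68.7% of summits were upstream of it. Divergent or closely spaced genes shared 334 summits, while 313 summits were over 5000 bp from any 5′ end. Both windows tried, shorter and longer, left the promoter share above all random placements.

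**Figure D2:**
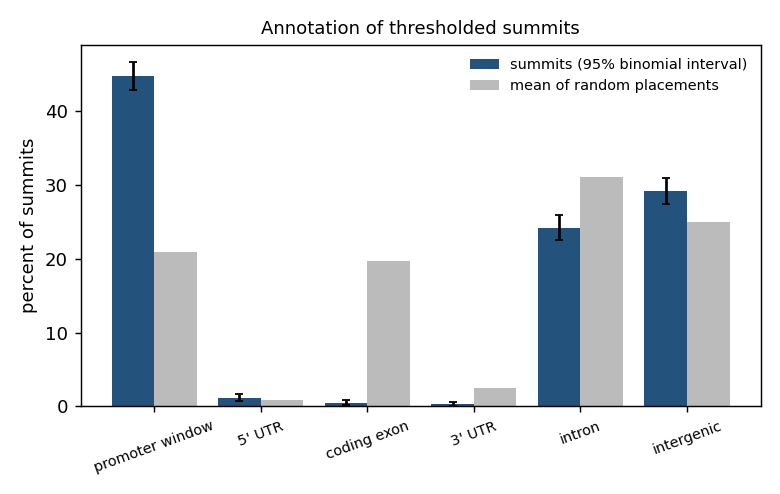
Share of the 2575 thresholded summits in each annotation class (blue, percent, with 95% exact binomial intervals) and the mean of 100000 random placements (grey, percent). Promoter windows held 44.7% of summits against 20.9% at random, and coding exons 0.466% against 19.7%.

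Ribosomal protein genes and body wall muscle genes were bound far more often than other genes. A gene was called bound when a summit lay in its promoter window, and 1438 of 19973 protein-coding genes (7.20%) were. Of 78 ribosomal protein genes, 50 (64.1%) were bound, an odds ratio of 23.8 (95% interval 14.6 to 39.4) against all other genes (Fisher's exact test, adjusted p = 1.8e-36). Their strongest peaks were at rpl-3 (signal 882), rpl-35 (732), rpl-15 (624) and rps-19 (585). When each summit was given to the nearest 5′ end, 31 of 78 (39.7%) were bound (adjusted p = 1.5e-11, exact test). Of 46 genes for the structure of body wall muscle, 25 were bound, an odds ratio of 15.6 (8.36 to 29.4, adjusted p = 3.8e-16, Fisher's exact test). Examples were unc-112, which encodes a kindlin of the muscle attachment complex (signal 448), the myosin light chain gene mlc-2 (391), the actin gene act-3 (376) and mup-2, which encodes troponin T (325).

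A further 3 lists had more bound members. Heat shock and stress genes had 9 of 31 bound (odds ratio 5.30, adjusted p = 0.0015 by Fisher's exact test), led by the HSP70 gene hsp-1 (signal 615), the mitochondrial chaperonin gene hsp-60 (492), hsp-110 (260) and hsp-3 (258). Pan-neuronal genes had 8 of 35 bound (odds ratio 3.83, adjusted p = 0.013, Fisher's exact test), with the strongest peaks at the liprin gene syd-2 (372), unc-14 (370), maco-1 (219) and unc-16 (189). Heterochronic genes, which time larval cell fates, had 5 of 16 bound (odds ratio 5.88, adjusted p = 0.016, Fisher's exact test). These were nhl-2 (603), ain-1 (573), lin-14 (293), lin-46 (136) and lin-28, the last named after its value was seen. With only the 1287 peaks of highest signal, the adjusted p of the exact test was 0.17 for pan-neuronal genes (4 bound) and 0.095 for heterochronic genes (3 bound). With a window from 500 bp upstream to 100 bp downstream, 1 heterochronic gene was bound (adjusted p = 0.87, exact test). With the longer window tried, 15 of 35 pan-neuronal genes were bound (adjusted p = 3.7e-06), and by the nearest 5′ end 19 of 35 (adjusted p = 3.2e-10) and 8 of 16 heterochronic genes (adjusted p = 2.1e-04, all by Fisher's exact test).

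Serpentine receptor, F-box, C-type lectin and neuropeptide genes were bound less often than other genes. The receptor list was taken by gene names beginning with sr, so it may hold some genes that do not encode chemoreceptors. It had 9 of 1171 bound (odds ratio 0.0942, adjusted p = 3.3e-26 by Fisher's exact test), with the strongest peak at sre-23 (signal 454, within 200 bp of a snoRNA gene). F-box genes had 5 of 322 (odds ratio 0.201, adjusted p = 4.7e-05, exact test), led by fbxb-85. C-type lectin genes had 5 of 240 (odds ratio 0.272, adjusted p = 0.0033, exact test), led by clec-126, whose summit was within 200 bp of a tRNA gene. Neuropeptide genes had 2 of 140 (odds ratio 0.186, adjusted p = 0.016, exact test), led by ins-39. With only the 1287 peaks of highest signal, the adjusted p of the exact test was 0.052 for lectin genes and 0.25 for neuropeptide genes. When each summit was given to the nearest 5′ end, it was 0.080 for neuropeptide genes.

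The other 23 lists did not pass. In the main promoter window no member was bound among 44 intestine genes, 30 genes of the Notch and EGF pathways, 20 glia genes and 3 POU genes. By the nearest 5′ end 7 of 30 Notch and EGF genes (23.3%, against 9.61% of other genes, adjusted p = 0.062, exact test) and 2 intestine genes were bound, and with the longer window 4 and 1. The POU genes were ceh-18 itself, ceh-6 and unc-86. Collagen genes named col had 4 of 156 bound (adjusted p = 0.061 by Fisher's exact test), a list that passed in 5 of its alternatives. Among lists of cell fate regulators, the bound members with the strongest peaks were the muscle regulator hlh-1 (1 of 21 mesoderm and muscle transcription factors), tlp-1 (3 of 21 epidermal transcription factors), lin-14 (2 of 48 neuronal transcription factors), ceh-20 (2 of 13 Hox genes and cofactors), ceh-38 (4 of 63 homeobox ceh genes) and nhr-1 (13 of 269 nuclear hormone receptors). Among structural and tissue lists they were hmp-1 (1 of 33 epidermal junction genes), col-71 (2 of 39 cuticle genes), mup-2 (1 of 29 somatic gonad and sheath genes), tbx-2 (2 of 30 pharynx genes), daf-19 (3 of 44 ciliary genes), vha-8 (2 of 25 excretory genes) and snf-11 (1 of 20 neurotransmitter genes). For the remaining lists they were mex-1 (1 of 50 germline genes), his-67 (6 of 72 histone genes), wrt-3 (2 of 85 hedgehog-related and patched-related genes), mig-5 (3 of 30 Wnt genes) and tig-2 (2 of 21 TGF-beta genes). The summit at wrt-3 was within 200 bp of a snoRNA gene. With the strongest peaks of replicate 2 alone, none of the epidermal junction, pharynx and Hox genes was bound, and the peak of hmp-1 ranked 998 in replicate 1 and 3321 in replicate 2. Genes in near-identical copies, such as histones, share sequence, and how the authors placed reads that match several copies is not given in the sources used here.

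**Figure D3:**
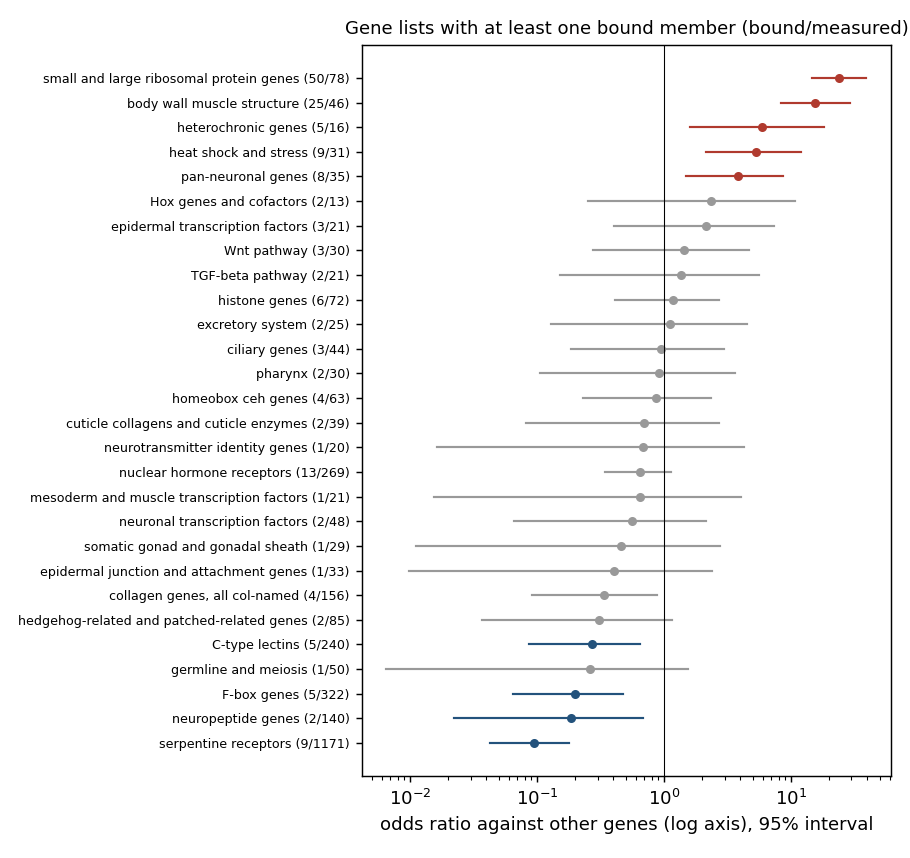
Odds ratio of being bound for each gene list with a bound member against all other protein-coding genes (points, log axis) with 95% intervals (lines). Numbers in parentheses are bound and measured members, red marks more and blue fewer bound members at adjusted p below 0.05, and ribosomal protein genes are highest at 23.8.

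Genes for small non-coding RNAs were also close to summits. Transfer RNA (tRNA) genes lay within 200 bp of 166 summits, or 6.45% (95% exact interval 5.53% to 7.47%), which was 21.7 times the mean of random placements. For snoRNA genes, which guide ribosomal RNA modification, there were 74 summits (2.87%, 15.6 times), and for snRNA genes 17 (0.660%, 11.2 times). Other non-coding RNA genes lay near 22.5% of summits (6.27 times). All of these had p = 1e-05 by permutation of summit positions, the smallest possible, and adjusted p = 1.7e-05. Long intergenic RNA genes (2.56 times, adjusted p = 3e-04), antisense RNA genes (2.65 times, adjusted p = 0.010) and microRNA genes (2.53 times, 8 summits, adjusted p = 0.018) were also near summits more often than in the permutation. The random positions covered whole chromosomes, including coding exons, where summits were rare. No control limited to non-coding sequence was used, so ratios of 2.53 to 2.65 cannot be told apart from a general preference for such sequence. Pseudogenes (0.140 times) and piRNA genes (0.229 times) were less often near a summit, and no summit was near a ribosomal RNA gene (permutation p = 1). Many tRNA, snoRNA and snRNA genes have near-identical copies, so the copy to which a peak belongs is uncertain.

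The word GAGAGA had the highest ratio between summits and flanks of the fixed motifs, and the octamer and its shorter form ATGCA did not pass. Within 75 bp of the summit, GAGAGA was present at 1163 peaks, or 45.2% (95% exact interval 43.2% to 47.1%), against 7.30% of windows 500 bp to either side, a ratio of 6.19 (adjusted p = 9.9e-200, exact McNemar test). The GC box GGGCGG was present at 10.4% against 2.62% (adjusted p = 1.3e-26), and the E-box CANNTG at 51.7% against 42.4% (adjusted p = 1.0e-11, both by the exact test). The octamer ATGCAAAT, the classical site of POU proteins, was present at 22 peaks (0.854%, against 1.36% in the flanks, adjusted p = 0.19, exact test). The wider form ATGCWAAT was at 25 (0.971%, against 1.71%, adjusted p = 0.14), and the shorter POU word ATGCA at 20.8% (against 20%, adjusted p = 0.54, both by the exact test).

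Words rich in A and T were less frequent at summits. The homeodomain word TAATTA was at 1.51% of peaks against 8.43% in the flanks (adjusted p = 1.4e-30, exact McNemar test), TAATGARAT at 0.0777% against 0.738% (adjusted p = 5.3e-04) and the GATA word WGATAR at 24.9% against 28.6% (adjusted p = 0.0038). The AP-1, T-box and FOX words did not pass, with ratios of 0.973, 1.27 and 1.2. Summit windows had a GC content of 47.6%, against 35.1% in the flanks. With dinucleotide-shuffled summit windows as the control, the ratio was 0.813 for TAATTA, which no longer passed (adjusted p = 0.35), and 1.2 for the GATA word, in the opposite direction (exact McNemar test). The FOX word then passed at 1.89 and TAATGARAT no longer did (adjusted p = 0.39, exact McNemar test). Against the flanks, the TAATGARAT ratio was 0.105 in the main set, 0.211 for the strongest peaks of replicate 1 alone and 0.286 for those of replicate 2 alone, where it did not pass (adjusted p = 0.098, exact McNemar test), nor did it within 50 bp, with flanks at 1000 bp or with GC-matched windows. With GC-matched promoter windows of unbound genes, an alternative chosen after seeing the data, the E-box ratio was 1.03 (adjusted p = 0.64, exact McNemar test) and the GC box was at 10.4% against 8.60%, a ratio of 1.21 (adjusted p = 0.045). TAATTA was still less frequent than in those windows, at 1.51% against 2.49%, a ratio of 0.609 (adjusted p = 0.045, exact McNemar test). The FOX word was more frequent than in those windows, at 2.68% against 0.990%, a ratio of 2.71 (adjusted p = 5.0e-06, exact McNemar test).

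Of 2080 words of 6 bases, 885 were more frequent at summits than in the flanks and 676 less frequent (Fisher's exact test, adjusted p below 0.05). Here the flanks of all summits were pooled, so the pairing of each summit with its own flanks was not used, unlike in the motif test. After GAGAGA and the overlapping AGAGAG, the leading words that were more frequent included CGTCTC, at 26.1% of summits against 4.02%, and ACGCAG, at 21.7% against 3.09%. The leading words that were less frequent were AAAATT, at 19.2% against 57.4%, and TTAAAA, at 8.47% against 39.1%. With dinucleotide-shuffled windows 405 words were more frequent.

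**Figure D4:**
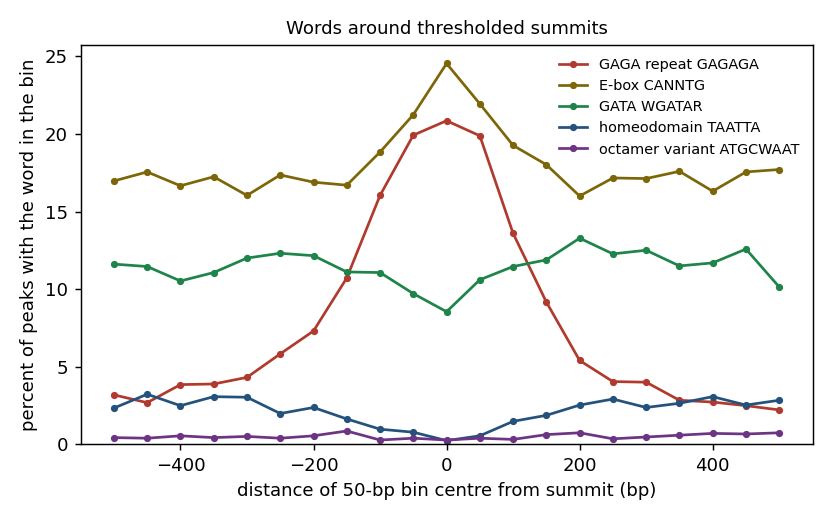
Percent of thresholded peaks with each word in 50-bp bins (y axis) by distance of the bin from the summit in bp (x axis), for 5 of the fixed motifs. GAGAGA and the E-box are highest in the bins at the summit, and TAATTA and the GATA word are lowest there.

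No thresholded peak lay within 20 kb of ceh-18 (X:3843367-3857797, minus strand), the gene whose product was tagged, nor of unc-119 (III:10902641-10908935, plus strand), which carries a mutation in this strain. A thresholded peak of signal 120.4, over III:10881947-10882431, lay just outside that distance from unc-119. A count of 0 is common, at the 22nd percentile, with a median of 1 around other protein-coding genes. Genes with equal counts share a middle rank in that percentile, so the share of genes with a count of 0 is larger than it. In the pooled list, which goes below the threshold, 9 peaks lay within 20 kb of ceh-18, against a median of 11 around other protein-coding genes. Their median signal of 34.9 was at the 32.3rd percentile, and that of the replicates' own lists at the 42.8th (replicate 1) and 79.7th (replicate 2). Around unc-119 there were 24 such peaks, at the 95.3rd percentile by number (96.8th in replicate 1 and 84.5th in replicate 2), with a median signal of 30.2 at the 10.5th percentile (14.7th and 24.4th). The 2 strongest of these 24, with signals of 81.04 and 72.3, lay within unc-119. Among genes with at least as many peaks the median around unc-119 was at percentile 0.771, while that of its 11 strongest peaks was at 49.9, among genes with at least 11. No peak of the pooled list or of either replicate lay over ceh-18 itself.

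**Figure D5:**
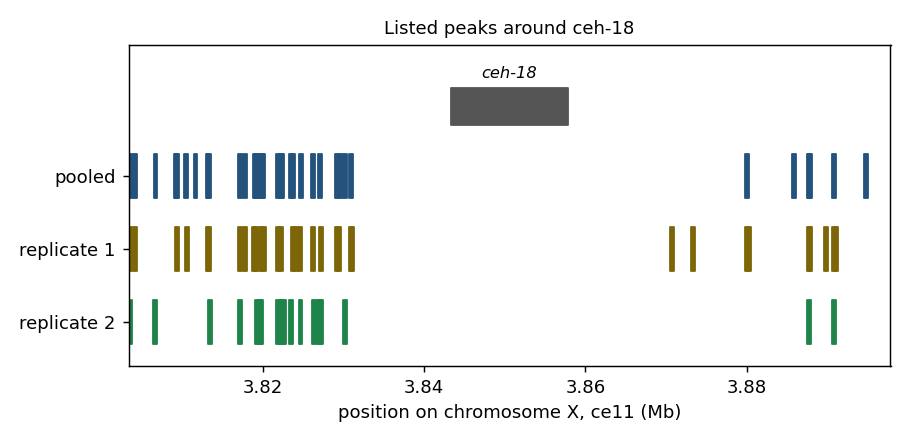
Peaks of the pooled list and of each replicate (coloured bars) around ceh-18 (grey bar) by position on chromosome X of the ce11 build in Mb. No peak is listed over the gene in any of the 3 lists, and the stretch without peaks in the pooled list is 48.7 kb long.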

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

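The test of peak spacing around ceh-18, the signal inside unc-119 and the GC-matched control were chosen only after the results were seen.

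Replicate 2 listed 14 peaks on the mitochondrial genome, where replicate 1 and the pooled list had 0, a signal in sequence that no comparison used. The strongest had a signal of 491 and ranked 4 in replicate 2's list.

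The summits held GAGAGA at 45.2% of peaks and the octamer at under 1%. Base composition alone may account for part of the GAGAGA share, since dinucleotide-shuffled windows held it at 23.1%, but the summits exceeded this by a ratio of 1.95 (95% bootstrap interval 1.82 to 2.10), and GC-matched promoter windows of unbound genes by a ratio of 3.25 (2.93 to 3.61), so neither explains all of it. For ATGCWAAT the ratio to shuffled windows was 0.893 (0.531 to 1.53), from 25 and 28 windows, too few to exclude an excess of 1.2. Among the 25891 weaker peaks of the pooled list the ratio to the flanks was 1.14 (1.02 to 1.28, exact McNemar p = 0.021). Both ratios were under the bound of 1.2 set beforehand. By that rule the first counted for base composition, and the second against octamer binding among weaker peaks. Both were left open only because their bootstrap intervals, which the rule did not use, reach above 1.2. No precipitation from worms with GFP alone was analysed here, so a biological explanation of the GAGAGA sites, or one through open chromatin at active genes, was not tested.

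The 5 gene lists with more bound members were weighed against longer upstream sequence. The promoter window has a fixed length, so longer upstream sequence can only leave more of it free of neighbouring genes. Calls by the nearest 5′ end, where such length could matter more, were not matched on it. Against 10000 random lists matched on upstream intergenic distance, 5 of 5 kept an adjusted p below 0.05, which argues against it as the whole cause. Summits at small RNA genes beside ribosomal protein genes could also have raised that list, but without the 256 summits within 200 bp of a tRNA, snoRNA or snRNA gene 62.8% of ribosomal protein genes were still bound (49 of 78, adjusted p = 3.8e-36 by Fisher's exact test). High expression of these genes was not tested and stays open.

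The peak-free stretch over ceh-18 and the signal around both transgene loci were weighed together. For ceh-18 the median pooled signal was at the 32.3rd percentile (42.8th in replicate 1, 79.7th in replicate 2), below the bound of 75 set beforehand as counting against extra copies, which were left open only once it was seen that the 9 pooled peaks lay on 1 side, at least 12.2 kb from the gene. For unc-119 it was at the 10.5th (14.7th and 24.4th), also below that bound, and extra copies were left open only once the 5 summits inside the gene, far narrower than the window, were found at percentile 79.6 (78.5 and 84.4), between 75 and the 95 that would have favoured them. The stretch, X:3831127-3879821, is 48.7 kb long, with 8 longer among 4100 on X, and stretches at least this long make up 3.11% of X (for replicate 1's own stretch of 39.1 kb 3.05%, and for replicate 2's of 56.96 kb 1.91%). Ordinary spacing was first to be set aside below 5%, which was lowered to 1% once the value was seen, since this is a single picked stretch, so it cannot be told apart from a cause tied to the locus, and a control with the same extra copies, or removal of the region by the authors, was not tested.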

How the results depend on the processing

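Of the main results paired with each alternative, 67 pairs were labelled as kept and 20 as moved. A test was kept if its direction and side of the threshold held, and an overlap or correlation if it stayed within its error. Counts were kept if they changed by no more than a set fold, without any error or test. The ce10 set of 3485 peaks against 2575 was therefore labelled as kept, which is a loose standard. The strongest peaks of the pooled list and the merging of summits left the peaks as they were and say nothing about stability. The GC-matched control and the removal of summits near small RNA genes were chosen after seeing the data. The stricter set held 1287 peaks by construction. Overlap with replicate 1 was 99.3% for at least 50% of the peak, 98.4% for summits within 100 bp, 90.02% for the replicate's strongest peaks only and 99.9% in the stricter set, and with replicate 2 it was 98.9%, 98.6% and 90.5% for the first 3 of these. The Spearman coefficient was 0.732 with summits within 100 bp. In the stricter set, with fewer peaks, 3 lists had more and 2 fewer bound members. With shuffled windows 5 motifs were more and 0 less frequent, with flanks at 1000 bp 1 was less frequent, and with GC-matched windows 1 was. The GATA word turned from fewer to more, with a ratio of 1.2 against shuffled and 1.34 against GC-matched windows. More frequent words numbered 405 with shuffled and 434 with GC-matched windows, and 4649 of 8 bases were more and 3221 less frequent, out of more words tested. Within 40 kb of unc-119 there was 1 thresholded peak. For the other moved values the cause was not tested. Of the single lists, motifs and gene types, 15 pairs fell short of the threshold they had passed (pan-neuronal, heterochronic, neuropeptide and lectin genes and the TAATGARAT, TAATTA, GATA and E-box words), 12 newly passed it (col, nuclear hormone receptor, TGF-beta, germline and hedgehog-related genes and the FOX word) and 395 kept their side. Unknown depth limits any statement on peaks that were not listed.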

Other observations

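The lists and ranks below were examined only after the main results were seen.

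Peaks of the pooled list below the threshold, 25891 in all, included 2437 with a -log10 q of at least 2, and were compared with the same gene lists. Wnt pathway genes were bound more often than other genes by these weaker peaks, 19 of 30 (odds ratio 3.93, adjusted p = 0.0015 by Fisher's exact test) as were homeobox ceh genes, 32 of 63 (2.35, adjusted p = 0.0046). For both lists, 30.5% of other genes were bound by these peaks, so such a call is common. The pooled list also holds background. Random lists matched on upstream distance were not drawn for these peaks, so longer upstream sequence was not tested here. Genes of the Notch and EGF pathways, none bound in the main window by thresholded peaks, had 16 of 30 bound (2.60, adjusted p = 0.028, exact test), as did pharynx genes (16 of 30). Body wall muscle genes had 30 of 46 bound (4.27, adjusted p = 2.5e-05) and pan-neuronal genes 19 of 35 (2.7, adjusted p = 0.019, exact test). Intestine genes were bound less often, 5 of 44 (odds ratio 0.290, adjusted p = 0.019), as were serpentine receptor genes, 89 of 1171 (0.175, adjusted p = 1.0e-84, exact test). Ribosomal protein genes did not pass (33 of 78, adjusted p = 0.066, exact test). The weaker set leaves out the thresholded peaks, by which 50 of these 78 were bound. Peaks ranked 2576 to 5000 bound 14.1% of ribosomal protein genes against 5.84% of all genes, and those ranked 20001 to 28466 bound 7.69% against 9.33%.

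Along the ranking of the pooled list, GAGAGA fell from 45.2% of thresholded peaks to 34.4% of peaks ranked 2576 to 5000 and 11% of those ranked 20001 to 28466. The flanks held it at between 7.27% and 7.51%. The promoter share fell from 44.7% to 20.8% between the same ends, the latter near the mean of 20.9% for random placements of thresholded summits. TAATTA rose from 1.51% to 5.81% but stayed below its flanks, which held it at 8.43% and 6.99%. The GC content of summit windows fell from 47.6% to 40.3% between these ends.

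The thresholded set was larger in ce10, with 3485 peaks against 2575. The ce10 pooled list held 2576 peaks at or above the lowest thresholded ce11 signal. The 910 ce11 peaks ranked 2576 to 3485 had a promoter share of 42.2%, above the highest of 100000 random placements (27.1%). Of them, 99.7% were overlapped in replicate 1 and 99.6% in replicate 2.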
